A study of Mus musculus with 24 samples.

How the data were processed

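RNA of 24 mouse livers, 1 library per mouse, was sequenced after poly-A selection by the submitters of the study. Per the labels, reads were called with CASAVA and aligned with HISAT2 to the mouse genome GRCm39, and DESeq2 was among the tools; their versions, the program that counted reads, the annotation release and the strandedness are not given in the sources used here. The data came as 3 deposited tables of 12 libraries each. The deposited counts are raw reads per gene. The deposited FPKM values are counts scaled by gene length in kilobases and by the number of reads in genes. The deposited signal values are counts divided by 1 size factor per library, set within each table. The deposited gene length is in bases and was used by the authors for FPKM, a unit of its own kind (other). Only the counts were used for tests; FPKM, signal and gene length were read only to check the units.

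The tables listed 25892, 25229 and 25027 genes and were joined on the gene identifier to 27802 genes, 22794 of them in all 3 tables. Counts of libraries present in more than 1 table were identical (0 differences). A gene was absent from a table when its 12 libraries held fewer than 2 reads, and its 40326 missing values were set to 0. Gene positions are those of the deposited tables. Depth was 21691653 to 34851108 reads in genes. Counting intervals are not given, as variation between mice exceeded counting error: the chi-square per degree of freedom between libraries of a group was 27.3 to 421. CPM are counts scaled to a common library size after TMM scaling of library sizes, given as mean ± SD over mice.

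Libraries were grouped by temperature, ablation and sex into 8 groups per the labels. Genes with low counts were removed with filterByExpr, which left 20213, and tested with edgeR 4.0.16 (TMM, trended dispersion, robust quasi-likelihood F test, 16 residual degrees of freedom) on the 8 group means. All tests were two-sided, p was adjusted by Benjamini and Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Effects are log2 fold changes averaged over both sexes, with an SE computed as the size of the log2 fold change over the square root of F. The comparisons were ablation at 22 °C and at 30 °C, temperature (22 °C over 30 °C) in controls and in ablated mice, the difference of the ablation effect between temperatures and between sexes (females minus males) at each temperature, and the sex difference in controls. The direction per library was taken against the mean of the opposite condition in the same sex.

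The 37 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, again with a correlation estimated from the data, and with fry, each adjusted over the lists of a comparison. Counts adjusted over the list alone apply the adjustment to the members of 1 list. The lists were written from general knowledge, and some share genes, such as Gsta1 in NRF2 targets and drug-metabolising enzymes. The comparisons, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named, for ablation at each temperature and for temperature in controls, the 10 largest rises and 10 largest falls among called protein-coding genes with an average log2 CPM of at least 0, all where there were fewer, and the 5 of lowest p where there were none. For temperature in ablated mice and the differences of effects it named 5 and 5. For the sexes it named Xist, Ddx3y, Kdm5d, Eif2s3y and Uty and the 3 largest autosomal differences each way. It further named up to 4 members of each list that was called or had at least 3 called members, and in every comparison Agtr1a, Agrp, Agt, Fgf21, Cyp7a1, Igf1, Pck1, Fasn, Cirbp and Rbm3. Some genes under this rule are not reported here. Other genes named, among them Gm3734 and further list members, were chosen after their values were seen.

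The called genes of each comparison were counted anew with DESeq2 size factors, with no filter, with an absolute log2 fold change of at least 1, with the replicate number as a block, and without each library of the groups compared in turn. DESeq2 1.42.0 was run in place of edgeR without the low-count filter, with its own filtering (27787 genes), so that tool and filter changed together. Fits of only the groups compared were filtered anew and were not made for the difference between temperatures. Sex as an additive term, no sex term, a term for Cre, and Cre-negative controls alone were run for ablation and temperature and for the difference between temperatures, not for the differences between sexes. Ai39 x BAC-AT1A-Cre mice alone were run for the same except ablation at 22 °C, where all mice are of that line. The fits of Cre-negative controls and of Ai39 x BAC-AT1A-Cre mice also took sex as additive and were filtered anew (18496 and 18708 genes), so that each changed more than 1 choice. Single lists and named genes were recomputed under the alternatives of their comparison, except the fold change threshold and, for lists, DESeq2. The number of called lists was counted only where all 8 comparisons were fitted, and the overlap only where both ablation effects were. After the data were seen, limma voom with quality weights and a fit without the 3 libraries with most genes at 0 reads were added. For 100 splits of the libraries per comparison, the real one included, calls were counted anew. The procedure was tested on simulated data with 200 genes changed, 100 by 2-fold and 100 by 4-fold, and 1 further list of genes shifted, whose called members count neither as false nor among the 200. For ablation at 22 °C it called 54% and 87% of them, with 7 false among 156 calls; for the sex-specific effect at 22 °C it called 8% and 57%, with 5 false among 70. With no gene changed it made 1 call. The 200 genes averaged at least 1 CPM, and apart from the changes all libraries shared the same means. Sex differences, correlation between genes and a library with many genes at 0 reads were not simulated, so these rates may not hold for the real libraries. Calculations used R 4.3.3, Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Food intake, metabolic rate and blood pressure, to which the title of the study refers, were not analysed here.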

Results

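Messenger RNA of the liver was sequenced from 24 adult mice, 1 library per mouse, in a design that crossed ablation, housing temperature and sex. A viral vector carrying a Cre-dependent construct that kills cells was injected into the arcuate nucleus of mice that express Cre from an angiotensin receptor (Agtr1a) transgene, to remove the AgRP neurons that bear this receptor. What the control mice were injected with is not given in the sources used here. Mice were then kept at 22 °C, below mouse thermoneutrality, or at 30 °C, and the liver was frozen 2 weeks after surgery. At 22 °C each of the 4 groups of ablated and control males and females held 3 mice. At 30 °C there were 3 ablated males, 3 ablated females, 2 control males and 4 control females. All ablated mice carried Cre, whereas 4 controls carried it and 8 did not. Among controls at 22 °C only male 1 carried it, and no female did. Among controls at 30 °C both males carried it, and of the females only female 4. All 12 mice at 22 °C were labelled Ai39 x BAC-AT1A-Cre (genotype Halo+/-). Of the 12 at 30 °C, 7 were too, while 2 were labelled Ai9 x BAC-AT1A-Cre and 3 BAC-AT1A-Cre. Both Ai9 x BAC-AT1A-Cre mice were ablated, so no control was of that line.

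The libraries held 21691653 to 34851108 reads in genes, and 13601 to 16682 genes had at least 10 reads. Of 20213 genes tested, 1667 to 3970 had no reads in each library but 1. The library of 30 °C control male 1 had no reads for 6372 of them and lay far from the others on the first principal component (-187.4), although it held 24155676 reads. Mitochondrially encoded genes took 7.53% to 37.3% of the reads, with the lowest share in 30 °C ablated female 3 and the highest in 22 °C control female 3. The share was 26.0% ± 5.62 in control males and 23% ± 12.5 in control females at 22 °C (SD, n = 3 each). It was 18.6% ± 0.803 in ablated males and 22.6% ± 4.68 in ablated females at 22 °C (n = 3 each). At 30 °C it was 12% ± 3.85 in ablated females (n = 3) and 15.4% ± 4.61 in control females (n = 4). It was 19.2% ± 1.26 in ablated males (n = 3) and 20.4% ± 4.79 in control males (n = 2) at 30 °C.

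**Figure D1:**
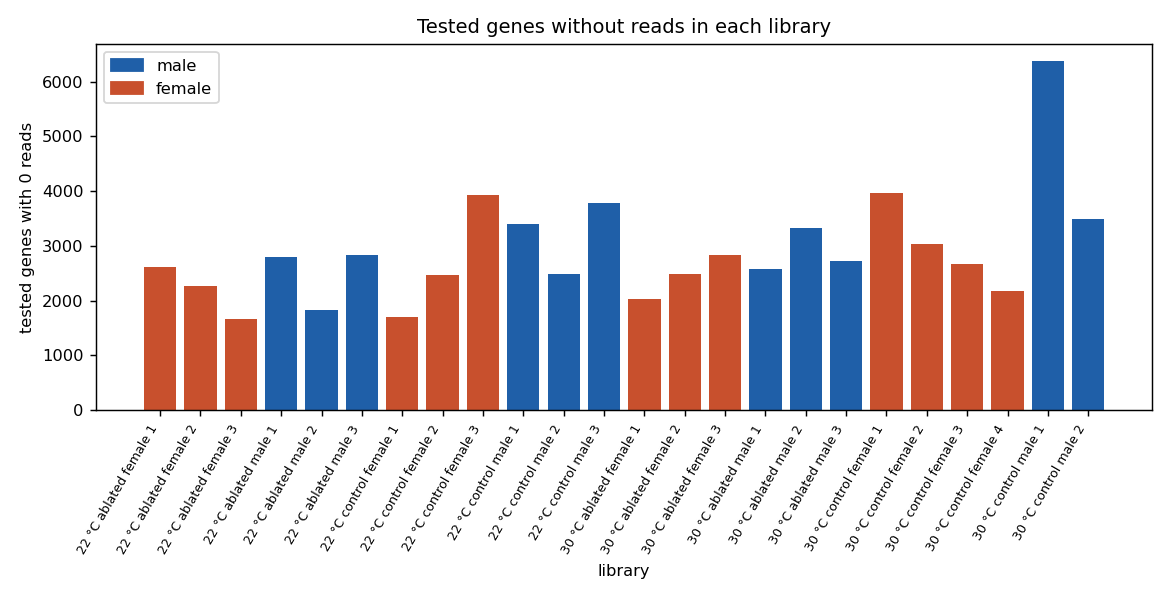
Number of the 20213 tested genes with 0 reads (vertical axis) in each of the 24 libraries (horizontal axis), coloured by sex. The library of 30 °C control male 1 lacked reads for 6372 genes, and the others lacked them for 1667 to 3970.

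The sexes differed as their labels state. In controls, averaged over both temperatures, 568 genes differed between females and males, 320 higher in females and 248 higher in males (edgeR, n = 7 females and 5 males). A larger share of the control males than of the control females carried Cre, so Cre is in part mixed with sex. No fit with a Cre term was made for this comparison. Of the Y chromosome genes, Kdm5d had 0 reads in all 7 control females and 12.2 to 23.4 CPM in control males, and Ddx3y, Uty and Eif2s3y were lower in females, with log2 fold changes of -12.84 ± 0.45, -10.11 ± 0.64 and -9.79 ± 0.39. Xist, the transcript that silences an X chromosome in females, was higher by 8.81 ± 0.82 on the log2 scale (adjusted p = 5.13e-06). Of 25 measured female-biased liver genes, 24 were called higher in females (median log2 fold change 7.90), and of 26 male-biased genes 20 were called lower (median -5.27). These lists gave adjusted p = 2.89e-60 and 6.88e-56 with the preset correlation, and adjusted p = 2.74e-05 and 0.00224 with an estimated correlation. The angiotensin receptor gene Agtr1a and angiotensinogen (Agt), both made by hepatocytes, were higher in females by 0.60 ± 0.12 (adjusted p = 0.00218) and 0.61 ± 0.15 (adjusted p = 0.0163). The metallothionein Mt1 was higher by 2.90 ± 0.42 (adjusted p = 0.000374). Of the largest autosomal differences, the sulfotransferase Sult3a1 stood at 69.3, 104, 34.1, 16.7, 65.9, 105 and 29.4 CPM in control females and at 0 in control males, and Cyp3a16 and Hao2 also had 0 reads in all 5 control males. The pheromone-binding protein gene Mup7 was lower in females with a log2 fold change of -11.78 (adjusted p = 0.00221), and so was the fatty acid hydroxylase Cyp4a12a with -9.17 (adjusted p = 5.48e-05), while Scara5 had 0 reads in all 7 control females. With the preset correlation, lists higher in females were cholesterol synthesis (0.00685), fatty acid oxidation (0.00808), the acute phase (0.0091), the cell cycle (0.014) and the renin-angiotensin system (0.0452). Lower were mitochondrially encoded (0.000972), erythroid (0.00199) and adipocyte genes (0.00685), and these 8 lists had adjusted p of at least 0.288 with an estimated correlation. Igf1 (0.01 ± 0.15) and Fasn (0.13 ± 0.23) were not called. The count was 319 without 30 °C control male 1, 1732 without 30 °C control male 2, and 1119 with DESeq2 and 971 with edgeR when both ran without the low-count filter.

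The first question was what ablation changed in the liver of mice kept at 22 °C, where the body must produce extra heat. In 6 ablated against 6 control mice, 19 genes changed, 9 higher and 10 lower in ablated mice. Gsta2, a glutathione transferase, rose from 9.65 ± 4.31 to 43.9 ± 22.8 CPM (counts scaled to a common library size; mean ± SD, n = 6 each), a log2 fold change of 2.27 ± 0.30 (SE; adjusted p = 0.00232). Scd2, which desaturates fatty acids, rose from 1.77 ± 1.24 to 10.7 ± 5.91 CPM, by 2.60 ± 0.42 (adjusted p = 0.00579). Il1rn, the secreted antagonist of the interleukin-1 receptor, rose from 2.30 ± 1.76 to 7.21 ± 1.28 CPM, by 1.95 ± 0.35 (adjusted p = 0.00851). Slc22a7, a hepatic transporter of organic anions, fell from 50.2 ± 32.7 to 8.53 ± 4.31 CPM, a log2 fold change of -2.50 ± 0.40 (adjusted p = 0.0132).

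The metallothionein Mt1 rose by 2.21 ± 0.37 (adjusted p = 0.02). Cdkn2c, which inhibits the cell-cycle kinases CDK4 and CDK6, rose by 1.35 ± 0.21 (adjusted p = 0.00232). The other rises were in Ugdh, which makes the sugar donor for glucuronidation (0.84 ± 0.17, adjusted p = 0.0334), and the ethanolamine kinase Etnk1 (0.58 ± 0.11, adjusted p = 0.02). Gsta1 stood at 20.4 ± 20.9 CPM in ablated and 0.488 ± 0.547 CPM in control mice (adjusted p = 0.0334), and its paralog Gm3776 at 6.03 ± 6.25 and 0.183 ± 0.298 CPM (adjusted p = 0.00579). At 22 °C each had 0 reads in 2 of 3 control females. Gsta1, Gsta2 and Gm3776 are neighbouring paralogs on chromosome 9, and how reads shared between them were counted is not given in the sources used here. Among the genes that fell were Nxpe2 (-1.47 ± 0.19, adjusted p = 0.000289), Npr2, the receptor for C-type natriuretic peptide (-1.32 ± 0.23, adjusted p = 0.0121), and the imprinted gene Peg3 (-1.16 ± 0.20, adjusted p = 0.00798). The carboxylesterase Ces3a fell from 1770 ± 882 to 1050 ± 790 CPM (-1.03 ± 0.19, adjusted p = 0.0097). Gba2, a non-lysosomal glucosylceramidase, fell by 0.81 ± 0.14 (adjusted p = 0.00812). The set was completed by Tedc2 (-1.36 ± 0.22), the endoplasmic reticulum protein gene Creld2 (-1.02 ± 0.19), the protein disulfide isomerase-like gene Pdilt (-1.07 ± 0.22) and the long non-coding RNA Gm3734 (-2.62 ± 0.40). Their adjusted p were 0.00798, 0.0132, 0.0334 and 0.00997. Each gene moved the same way in 6 of 6 ablated libraries against the mean of control libraries of the same sex, except Gm3734, which did so in 5 of 6. The genes were called in these same libraries, so this agreement is no separate evidence.

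**Figure D2:**
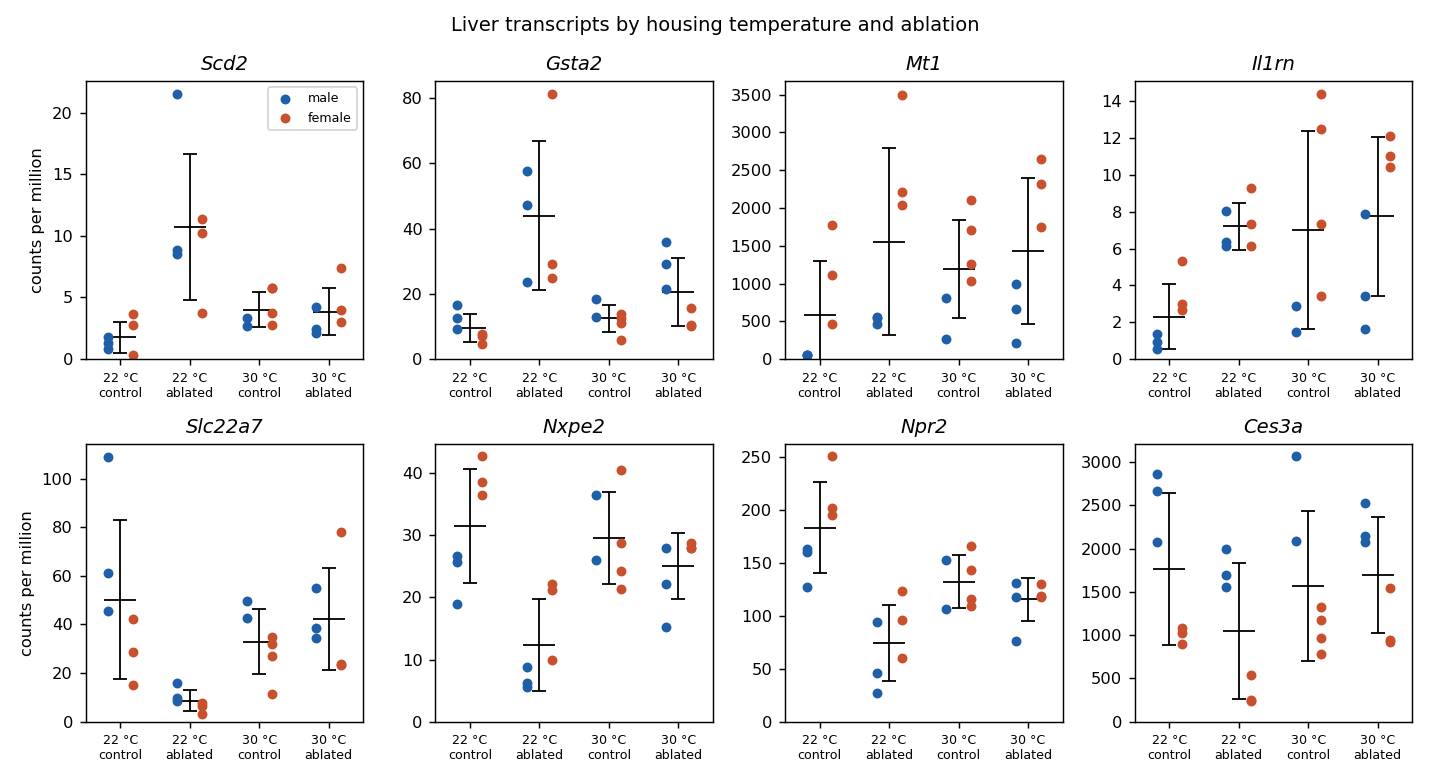
CPM (vertical axes, linear, each with its own scale) of 8 genes called for ablation at 22 °C, in every library, by temperature and ablation (horizontal axis); points are mice coloured by sex, and bars give the mean ± SD of both sexes together (n = 6). Slc22a7 averaged 8.53 CPM in ablated mice at 22 °C and 33.0 to 50.2 CPM in the other conditions.

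In GRCm39 coordinates of the deposited annotation, Gsta2 (ENSMUSG00000057933) lies on chromosome 9 at 78238300 to 78263070, Scd2 (ENSMUSG00000025203) on chromosome 19 at 44282113 to 44295303, and Il1rn (ENSMUSG00000026981) on chromosome 2 at 24226865 to 24241506. Slc22a7 (ENSMUSG00000067144) lies on chromosome 17 at 46743109 to 46749383, Nxpe2 (ENSMUSG00000032028) on chromosome 9 at 48229306 to 48264754, and Npr2 (ENSMUSG00000028469) on chromosome 4 at 43631935 to 43651244. Nxpe2, Cdkn2c, Tedc2, Gba2, Ces3a, Npr2, Etnk1, Ugdh and Pdilt overlap at least 1 other annotated gene, and the strandedness of the libraries is not given in the sources used here.

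Of the lists fixed before the data were examined, 17 of 37 were called for ablation at 22 °C with camera's preset correlation, and none was with an estimated correlation (lowest adjusted p = 0.269 with an estimated correlation). Targets of the oxidative stress regulator NRF2 were higher as a group (16 of 19 positive, adjusted p = 1.89e-06; adjusted p = 0.269 with an estimated correlation). Of these 19, 2 were called over all genes and 7 passed when adjusted over the list alone, all higher: Hmox1, Srxn1, Gsta1, Gsta2, Gsta4, Gstm1 and the exporter Abcc4. Acute phase genes were higher as a group (12 of 22 positive, median 0.11, adjusted p = 0.000212; adjusted p = 0.458 with an estimated correlation). Of these, Mt1 and Il1rn were called over all genes, and Saa2, Saa3, Mt1, Mt2 and Il1rn passed when adjusted over the list alone. Saa3, a serum amyloid A gene, had a log2 fold change of 1.44 ± 0.31 (adjusted p = 0.0594 over all genes).

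Genes of fatty acid oxidation and ketogenesis were higher as a group (25 of 30 positive, adjusted p = 0.003; 0 called over all genes and 5 adjusted over the list alone; adjusted p = 0.503 with an estimated correlation). These 5 were Cyp4a14, Ehhadh, Pdk4, Acot2 and Plin2. Cyp4a14, which hydroxylates fatty acids, stood at 207 ± 125 CPM in ablated and 52.5 ± 53.9 CPM in control mice (log2 fold change 2.67 ± 0.55, adjusted p = 0.101 over all genes). Cell cycle genes were higher as a group (22 of 26 positive, adjusted p = 9.6e-05; 1 adjusted over the list alone; adjusted p = 0.409 with an estimated correlation). The proliferation marker Mki67 stood at 10.9 ± 4.90 against 2.77 ± 1.48 CPM (adjusted p = 0.152). Markers of cells other than hepatocytes were also higher as groups. This held for stellate cells and fibroblasts (adjusted p = 0.0017), lymphocytes (0.0137), macrophages (0.0354) and cholangiocytes (0.0364), with adjusted p = 0.503, 0.458, 0.624 and 0.542 with an estimated correlation. Endothelial markers were not called (adjusted p = 0.4).

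Male-biased liver genes were lower as a group (21 of 26 negative, median -0.81, adjusted p = 1.21e-05; 2 adjusted over the list alone, Mup3 and Slco1a1; adjusted p = 0.458 with an estimated correlation). Pericentral genes were lower as a group (14 of 17 negative, adjusted p = 0.000132; adjusted p = 0.409 with an estimated correlation). Glutamine synthetase (Glul) was at -0.92 ± 0.25 (adjusted p = 0.232). Genes of bile acid synthesis and transport (15 of 20 negative, adjusted p = 0.000774) and cholesterol synthesis (21 of 25 negative, adjusted p = 0.00372) were lower as groups, with adjusted p = 0.269 and 0.561 with an estimated correlation. So were genes of the unfolded protein and integrated stress response (16 of 20 negative, adjusted p = 0.00727; adjusted p = 0.458 with an estimated correlation). Of these, Creld2 was called over all genes and the chaperone genes Hyou1 and Manf also passed when adjusted over the list alone. All 13 mitochondrially encoded genes were negative (median -0.38, adjusted p = 0.00243; adjusted p = 0.545 with an estimated correlation). Circadian clock genes (13 of 18 negative, adjusted p = 0.0124; adjusted p = 0.458 with an estimated correlation) included Per1 and Per2, which passed when adjusted over the list alone. Growth hormone signalling (9 of 13 negative, adjusted p = 0.0364; adjusted p = 0.269 with an estimated correlation) and gluconeogenesis and glycogen (12 of 19 negative, adjusted p = 0.049; adjusted p = 0.503 with an estimated correlation) were the remaining called lists.

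Of 25 drug-metabolising enzymes, 4 were higher and 5 lower when adjusted over the list alone, while the other 16 did not pass. The list was not called in 1 direction (camera adjusted p = 0.739), and fry called a change in either direction (adjusted p = 2.05e-05). The higher genes were Gsta1, Gstm1, Gstm3 and Cyp2b9, and the lower genes were Cyp2c37, Cyp2c50, Cyp2c54, Cyp1a2 and Nr1i3, the nuclear receptor CAR. Lists not called by camera were fatty acid synthesis (adjusted p = 0.241), glycolysis (0.0614), heat shock proteins (0.0614), p53 response and apoptosis (0.0614), erythroid genes (0.0582) and nuclear-encoded oxidative phosphorylation (0.106). Further lists not called by camera were amino acid catabolism and urea cycle (0.121), female-biased liver genes (0.164), thyroid hormone response (0.182), skeletal muscle genes (0.182), interferon response (0.502), neutrophil and platelet genes (0.502) and periportal genes (0.634). The same held for serine, one-carbon and methionine metabolism (0.726), cytosolic ribosomal proteins (0.739), the renin-angiotensin system (0.739), exocrine pancreas genes (0.739) and adipocyte genes (0.87). Of these, fry called a change in either direction for p53 response and apoptosis (adjusted p = 0.00587), fatty acid synthesis (0.0161), female-biased (0.0206) and periportal genes (0.0311). No change was called in Agtr1a (60.1 ± 11.6 against 59.8 ± 13.7 CPM, log2 fold change 0.02 ± 0.11). Nor was it in angiotensinogen (-0.02 ± 0.14), the hepatokine Fgf21 (0.63 ± 0.65), the bile acid enzyme Cyp7a1 (-0.16 ± 0.35) or the cold-inducible RNA-binding protein genes Cirbp (0.21 ± 0.16) and Rbm3 (0.07 ± 0.16). Igf1 (-0.42 ± 0.14, adjusted p = 0.354), Pck1 (-0.84 ± 0.23, adjusted p = 0.226) and fatty acid synthase, Fasn (-0.38 ± 0.23, adjusted p = 0.687), were not called either.

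The count of 19 was 12 without 22 °C ablated male 2 or without ablated female 3, 49 without ablated male 3 and 185 with limma voom. Without the low-count filter it was 136 with DESeq2 and 400 with edgeR. It became 2 with no sex term and 0 with a term for Cre, which only 1 of 6 controls at 22 °C carried. Without each library in turn 10 of the 19 stayed called (Nxpe2, Cdkn2c, Gsta2, Gm3776, Scd2, Tedc2, Peg3, Gba2, Il1rn and Gm3734). The highest adjusted p of the others was 0.0623 for Ces3a, 0.0709 for Npr2, 0.0783 for Creld2, 0.0697 for Slc22a7, 0.0869 for Mt1, 0.0822 for Etnk1, 0.236 for Ugdh, 0.172 for Gsta1 and 0.184 for Pdilt.

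At 30 °C, close to mouse thermoneutrality, the question was whether ablation changed the liver when little extra heat was needed. No gene was called in 6 ablated against 6 control mice by edgeR (1407 at an unadjusted p under 0.05, lowest adjusted p = 0.122) or by limma voom. Without the low-count filter, DESeq2 called 47 and edgeR 74. Acute phase genes were higher as a group (21 of 22 positive, median 0.43, adjusted p = 0.000105; adjusted p = 0.93 with an estimated correlation). Of these 0 were called over all genes, and 3 passed when adjusted over the list alone. They were the serum amyloid gene Saa2 (41.8 ± 70.5 against 4.35 ± 1.55 CPM), orosomucoid Orm2 (65.4 ± 98.2 against 10.7 ± 5.99 CPM) and haptoglobin, Hp (3110 ± 1640 against 1890 ± 275 CPM; n = 6 each). Much of the spread lay in ablated female 3, with 184 CPM of Saa2 and 264 CPM of Orm2, the library with the lowest mitochondrial share. This mouse was Ai9 x BAC-AT1A-Cre, a line without controls.

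Endothelial markers (13 of 14 negative, adjusted p = 0.000105), stellate cell and fibroblast markers (13 of 16 negative, adjusted p = 0.00197) and mitochondrially encoded genes (13 of 13 negative, adjusted p = 0.00975) were lower as groups in ablated mice at 30 °C. Cytosolic ribosomal protein genes were higher (30 of 30 positive, median 0.18, adjusted p = 0.0468), and all of these had adjusted p = 0.93 with an estimated correlation. Without 30 °C control male 2 ribosomal protein genes were no longer called (median 0.097, adjusted p = 0.913) and lay below the other genes, whose median had risen. With Ai39 x BAC-AT1A-Cre mice alone and sex additive the median of stellate cell and fibroblast markers went from -0.283 to 0.033 (adjusted p = 0.958). The receptor gene Lyve1 of sinusoidal and lymphatic endothelium was at 0.901 ± 0.480 against 2.13 ± 1.20 CPM (adjusted p = 0.693). The genes of lowest p were Osbp2, Coro2a, Cd207 and Mdm1 (adjusted p = 0.122 each) and Fxyd7 (0.325), all with 0 reads in both control males. They stood at 1.75 ± 0.421, 1.83 ± 0.543, 1.19 ± 0.425, 2.34 ± 0.892 and 2.08 ± 1.68 CPM in ablated mice. Agtr1a (0.06 ± 0.12), Agt (0.26 ± 0.15), Fgf21 (-1.18 ± 0.68), Fasn (-0.09 ± 0.23), Pck1 (0.04 ± 0.24), Igf1 (-0.23 ± 0.15) and Cyp7a1 (-0.04 ± 0.36) were not called. Cirbp (0.44 ± 0.17) and Rbm3 (0.26 ± 0.17) were not called either, and all of these had adjusted p of 0.693 or more. The count of 0 became 817 without 30 °C control male 2, which left male 1 as the only control male and moved the median of all genes, and 1 without control female 1.

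Whether the effect of ablation depended on temperature was tested as the difference between both effects. No gene was called by edgeR (1414 at an unadjusted p under 0.05, lowest adjusted p = 0.391) or by limma voom. Without the low-count filter, DESeq2 called 14 and edgeR 191. The genes of lowest p were Slc22a7 (difference of log2 fold changes -2.77 ± 0.55), Nxpe2 (-1.19 ± 0.27), Scd2 (2.57 ± 0.58), the matrix gene Sned1 (-1.06 ± 0.25) and Rapgef5 (1.62 ± 0.38), each with adjusted p = 0.391. Scd2 stood at 3.86 ± 1.93 CPM in ablated and 4.00 ± 1.42 CPM in control mice at 30 °C, and Slc22a7 at 42.2 ± 21 and 33.0 ± 13.2 CPM (n = 6 each).

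With the preset correlation 9 lists were called for this difference, and none with an estimated one (lowest adjusted p = 0.683 with an estimated correlation). The effect at 22 °C was the higher for stellate cell and fibroblast markers (15 of 16 positive, adjusted p = 3.37e-06), endothelial markers (13 of 14 positive, 0.00133), NRF2 targets (15 of 19 positive, 0.00183) and fatty acid oxidation (21 of 30 positive, 0.00942). It was the lower for pericentral genes (15 of 17 negative, 0.00183), the unfolded protein response (15 of 20 negative, 0.014), erythroid genes (9 of 10 negative, 0.0236) and male-biased genes (21 of 26 negative, 0.0292), the last of which camera placed in the other direction without 30 °C control male 2 (median -0.486, adjusted p = 0.766). For female-biased genes it was the higher (15 of 25 positive, 0.0292). When adjusted over the list alone, Gsta1 and Gsta2 among NRF2 targets, Lyve1 among endothelial markers and Sdf2l1, Manf, Hyou1 and Creld2 of the unfolded protein response passed, the last 4 of them negative (-1.50 ± 0.47 for Sdf2l1). Agtr1a (-0.04 ± 0.16), Agt (-0.28 ± 0.21), Fasn (-0.30 ± 0.32) and Pck1 (-0.88 ± 0.33, adjusted p = 0.648) were not called. The count of 0 became 460 without 30 °C control male 2.

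The overlap of both ablation effects was counted next. As no gene was called at 30 °C by edgeR, 0 were shared at the adjusted threshold. At an unadjusted p under 0.01 the higher genes shared 5 (220 at 22 °C and 216 at 30 °C, 2.35 expected, Fisher's exact test, two-sided, p = 0.0876). The lower genes shared 4 (254 and 56, 0.704 expected, Fisher's exact test, two-sided, p = 0.00536). Of the 19 genes called at 22 °C, 16 had the same sign at 30 °C. Across genes, which are not independent replicates, the log2 fold changes had Pearson's r = 0.0617 and Spearman's rho = 0.055. Pearson's r was 0.365 with a term for Cre, which both effects then share, and 0.033 to 0.089 under the other alternatives run for it.

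Sex-specific effects of ablation at 22 °C were tested as the effect in females minus that in males (3 mice in each of 4 groups). No control female at 22 °C carried Cre and all ablated females did, so ablation and Cre cannot be told apart in females. No fit with a Cre term was made for this difference. Genes of fatty acid synthesis differed between the sexes as a group, with 16 of 21 positive, a median of 1.23 and adjusted p = 6.44e-10 (adjusted p = 0.206 with an estimated correlation). The list was not called by fry in 1 direction (adjusted p = 0.131) and was called by fry for a change in either direction (adjusted p = 0.000551). No member was called over all genes and 11 passed when adjusted over the list alone: Elovl6, Acacb, Acly, Pnpla3, Mlxipl, Acaca, Acot11, Acss2, Thrsp, Gpam and Fasn. These were chosen by their difference, so their signs in each sex are not independent of it. Of all 21 members, 15 had a log2 fold change below 0 in males when rounded to 2 decimals and 17 had one above 0 in females. An exception was Scd2, the member called for ablation at 22 °C, with 3.30 ± 0.62 in males and 1.90 ± 0.58 in females. Of 100 splits of the mice within sex, 21 gave some list as low an adjusted p and 7 gave some list as many members adjusted over the list alone.

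Elovl6, the elongase of palmitate, had a log2 fold change of -1.06 ± 0.31 in males (111 ± 23.5 against 231 ± 23.1 CPM) and 1.23 ± 0.31 in females (498 ± 327 against 213 ± 46.0 CPM; SD, n = 3 each), a difference of 2.29 ± 0.44 (adjusted p = 0.116 over all genes). ATP-citrate lyase, Acly, which supplies acetyl-CoA, had -1.27 ± 0.34 in males and 0.59 ± 0.33 in females (difference 1.86 ± 0.48, adjusted p = 0.324). The acetyl-CoA carboxylase gene Acacb had -1 ± 0.29 and 0.69 ± 0.29 (adjusted p = 0.271), and Fasn had -1.02 ± 0.32 and 0.25 ± 0.32 (adjusted p = 0.704). Mlxipl, the carbohydrate-responsive regulator of these genes, went from 1120 ± 42.7 to 638 ± 43.7 CPM in males (-0.82 ± 0.20), with 1070 ± 128 and 1170 ± 27.0 CPM in control and ablated females (0.13 ± 0.20). Srebf1, the sterol-responsive regulator, did not pass (difference -0.19 ± 0.28).

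**Figure D3:**
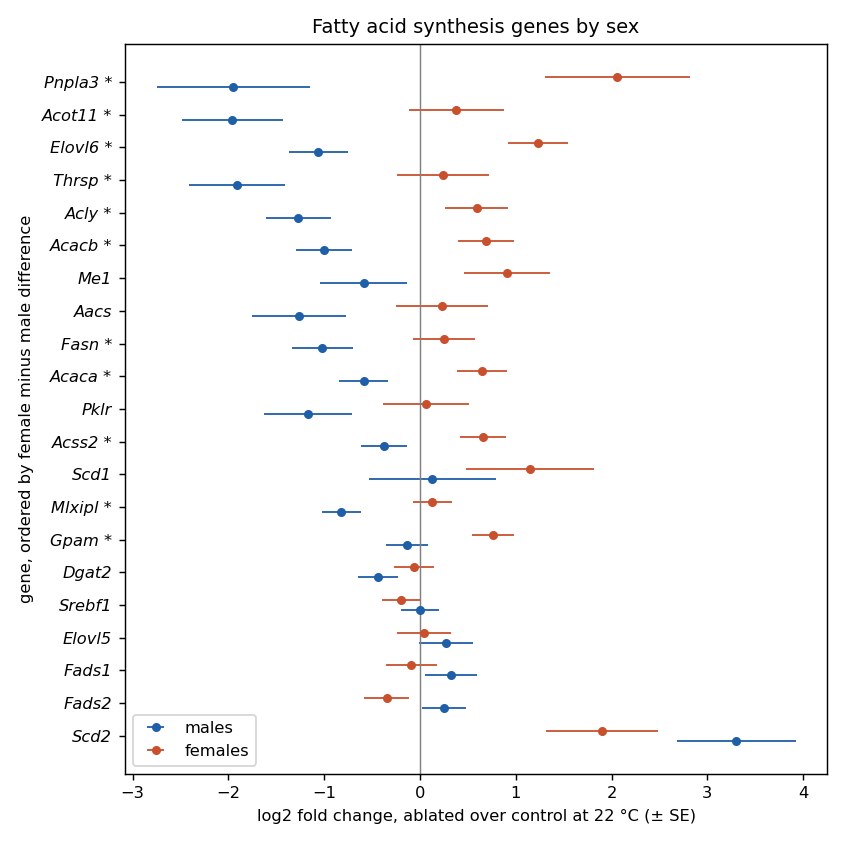
Log2 fold change of ablated over control mice at 22 °C (horizontal axis; bars are ± SE, 3 mice per group) for the 21 measured genes of fatty acid synthesis (vertical axis), males and females apart. An asterisk marks the 11 genes whose difference between the sexes passed when adjusted over the list alone.

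Pck1, which commits carbon to gluconeogenesis, stood at 577, 591 and 657 CPM in ablated females and 2050, 2470 and 2210 CPM in control females, with a log2 fold change of 0.21 ± 0.33 in males (difference -2.09 ± 0.47, adjusted p = 0.176). Pck1, Cdh1 and Etnppl passed when adjusted over the list of periportal genes alone, and 16 of 16 periportal genes had a negative difference, with a median effect of 0.34 in males and -0.42 in females (adjusted p = 2.16e-07; adjusted p = 0.332 with an estimated correlation). Sik1, a kinase induced by cAMP, had 1.36 ± 0.33 in males and -1.10 ± 0.33 in females (adjusted p = 0.116). The other genes of lowest p included Snhg11 (difference 4.28 ± 0.72) and Tle3 (2.09 ± 0.42), each with adjusted p = 0.116. All 10 erythroid genes had a positive difference (adjusted p = 1.71e-06; adjusted p = 0.206 with an estimated correlation), and Hbb-bs, Hba-a1 and Slc25a37 passed when adjusted over the list alone. Erythroid genes had a median log2 fold change of -1.59 in males and 0.48 in females.

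Further lists differed between the sexes in the effect of ablation, given here as the median log2 fold change in males and in females and the adjusted p of the difference with the preset correlation. The effect was less negative in females for mitochondrially encoded (-0.75 and -0.17, adjusted p = 0.000487) and pericentral genes (-0.58 and -0.07, 0.00359), and more positive for macrophage markers (0.16 and 0.77, 0.006). It was negative in males and near 0 in females for circadian clock (-0.33 and 0.03, 0.000937), glycolysis (-0.49 and 0.01, 0.0465) and drug-metabolising genes (-0.39 and 0.01, 0.0465). Its sign differed for adipocyte (-0.52 and 0.39, 0.0465) and neutrophil and platelet genes (-0.64 and 0.42, 0.0465). When adjusted over the list alone, the scavenger receptor gene Cd163 of macrophages, Gckr and Khk of glycolysis and Nr1i2 and Aldh1a1 of drug metabolism passed. Cfd and Car3 of the adipocyte list passed too. Both were also lower in control females than in control males (log2 fold changes of -8.92 and -1.09). Their place in this list does not show which cells made them. The effect was less positive in females for cell cycle genes (1.47 and 0.47, 0.0079), while acute phase (0.37 and -0.1, 0.000177) and female-biased genes (1.15 and -0.15, 0.0079) had a positive median in males and a negative one in females, with Cyp17a1, Abcd2, Cyp2a4 and Nipal1 of the female-biased list passing when adjusted over that list alone. All of these had adjusted p of at least 0.332 with an estimated correlation. No gene was called over all genes by edgeR (1265 at an unadjusted p under 0.05, lowest adjusted p = 0.116), and 116 were by limma voom. Without the low-count filter, DESeq2 called 54 and edgeR 249. The count became 5 without 22 °C control female 3, the library of the highest mitochondrial share, 4 without 22 °C ablated female 1, and 1 without ablated male 3, control female 1 or ablated female 3.

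At 30 °C the same difference between the sexes gave no called gene by edgeR (1343 at an unadjusted p under 0.05, lowest adjusted p = 0.0957) or by limma voom. Both control males carried Cre, but of the control females only female 4 did, so Cre is in part mixed with ablation in females. Without the low-count filter, DESeq2 called 59 and edgeR 98. The effect of ablation on acute phase genes was the higher in females, with a median log2 fold change of 0.12 in males and 0.72 in females (21 of 22 differences positive, adjusted p = 0.000137). The same held for male-biased (-0.4 and 0.47; 23 of 26 positive, 0.00298), heat shock (-0.13 and 0.21; 12 of 16 positive, 0.0214), interferon response (-0.11 and 0.03; 17 of 25 positive, 0.0214) and cytosolic ribosomal protein genes (0.08 and 0.3; 27 of 30 positive, 0.0214). Without 30 °C control male 1 the median difference of male-biased genes went from 0.901 to -0.311 (adjusted p = 0.707) and that of ribosomal protein genes from 0.231 to -0.053 (adjusted p = 0.972). All 5 had adjusted p = 0.989 with an estimated correlation, and no member was called. Saa1 had a difference of 3.63 ± 1.32 and Hp of 1.02 ± 0.36 (adjusted p = 0.742 and 0.729), with ablated female 3 again the highest. The genes of lowest p were Fxyd7 (adjusted p = 0.0957), Osbp2, Arl4c, Mgat4a and Jag2 (0.227 each), all with 0 reads in both control males, so no fold is given. Fasn (0.08 ± 0.46), Pck1 (-1.14 ± 0.48, adjusted p = 0.744), Agtr1a (-0.32 ± 0.24) and Igf1 (0.25 ± 0.29) were not called. The count became 813 without 30 °C control male 2, 2 without control female 1, and 1 without ablated female 1 or ablated male 3.

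The effect of housing temperature itself was tested in the 6 control mice at each temperature, as 22 °C against 30 °C. All 6 controls at 22 °C were Ai39 x BAC-AT1A-Cre and 1 of them carried Cre, whereas at 30 °C 2 of 6 were BAC-AT1A-Cre and 3 carried Cre, so line and Cre are in part mixed with temperature. There 7 genes differed, 6 higher and 1 lower at 22 °C. Sned1, a matrix protein gene, rose from 24 ± 6.69 to 49.5 ± 7.37 CPM (log2 fold change 1.11 ± 0.18, adjusted p = 0.0142). Lrp5, a Wnt co-receptor, rose from 28.3 ± 11.2 to 44.8 ± 8.26 CPM (0.88 ± 0.17) and Gse1 from 6.71 ± 2.07 to 16.3 ± 5.01 CPM (1.27 ± 0.24), while Zfand6 fell from 153 ± 12.5 to 103 ± 9.49 CPM (-0.57 ± 0.11; adjusted p = 0.0487 for each). Cd207, Rhof and Fxyd7 were called (adjusted p = 0.0487) at 1.55 ± 0.576, 1.74 ± 0.596 and 2.93 ± 1.38 CPM at 22 °C, but had 0 reads in both control males at 30 °C, so no fold is given.

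All 13 mitochondrially encoded genes were higher at 22 °C in controls (median 0.79, adjusted p = 3.13e-05), 10 of them when adjusted over the list alone and 0 over all genes. Among these, mt-Nd5, a subunit of respiratory complex I, stood at 16500 ± 7590 against 7480 ± 2580 CPM. The nuclear-encoded genes of oxidative phosphorylation were lower as a group (29 of 36 negative, median -0.15, adjusted p = 4.02e-05). Genes of fatty acid oxidation (24 of 30 negative, 0.000712), female-biased genes (18 of 25 negative, 0.00323), acute phase genes (18 of 22 negative, 0.0101) and drug-metabolising enzymes (19 of 25 negative, 0.0206) were lower as groups. All 6 lists had adjusted p = 0.989 with an estimated correlation. When adjusted over the list alone, Cyp4a14 and Acot1 of fatty acid oxidation, Mt1, Mt2 and Il1rn of the acute phase, and Cyp2b9 passed, all lower at 22 °C. Cirbp (0.09 ± 0.17), Rbm3 (0.05 ± 0.17), Agtr1a (0.28 ± 0.12, adjusted p = 0.329), Fgf21 (-0.14 ± 0.67) and Fasn (0.68 ± 0.24, adjusted p = 0.26) were not called, but without 30 °C control male 2 Fgf21 had 4.366 and was called (adjusted p = 0.0176). Of the 7 calls, 1 stayed with sex as an additive term, 1 with a Cre term, 1 with Ai39 x BAC-AT1A-Cre mice alone and sex additive, and 0 with Cre-negative controls alone and sex additive. None stayed without each library in turn. The count was 0 without 22 °C control male 1, male 3 or female 2 or 30 °C control male 1. It was 1 without 22 °C control male 2 or 30 °C control female 2, 2 without 22 °C control female 3 or 30 °C control female 4, and 4 without 22 °C control female 1. It was 15 without 30 °C control female 1 and 1687 without 30 °C control male 2. Voom called 0 genes, and without the low-count filter DESeq2 called 268 and edgeR 273.

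In ablated mice, 22 °C against 30 °C changed 7 genes, 2 higher and 5 lower at 22 °C (n = 6 each; all 6 at 22 °C and 3 of 6 at 30 °C were Ai39 x BAC-AT1A-Cre). Adamtsl2, a matrix protein that binds fibrillin, rose from 7.32 ± 2.70 to 24.2 ± 9.72 CPM (log2 fold change 1.66 ± 0.24, adjusted p = 0.00339). Gm3776, of the glutathione transferase cluster, stood at 6.03 ± 6.25 CPM at 22 °C and 0.282 ± 0.366 CPM at 30 °C (adjusted p = 0.00783). Lower at 22 °C were Slc22a7 (-2.39 ± 0.40, adjusted p = 0.0427), Nxpe2 (-1.17 ± 0.19, adjusted p = 0.00783), Ces3a (-1.04 ± 0.19, adjusted p = 0.0137), the scaffold gene Homer2 (-0.78 ± 0.14, adjusted p = 0.0137) and Adh7, an alcohol and retinol dehydrogenase (-0.74 ± 0.13, adjusted p = 0.0137). Each moved the same way in 6 of 6 libraries against the mean of the other temperature in the same sex, which is no separate evidence, as the calls came from these libraries.

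With the preset correlation 24 lists were called, 11 higher and 13 lower at 22 °C, and none with an estimated one (lowest adjusted p = 0.347 with an estimated correlation). Markers of non-hepatocytes were higher, namely stellate cells and fibroblasts (15 of 16 positive, median 1.02, adjusted p = 9.74e-10), endothelium (14 of 14 positive, 2.46e-06), lymphocytes (0.00304), cholangiocytes (0.006) and macrophages (0.038). With Ai39 x BAC-AT1A-Cre mice alone and sex additive, the median of macrophage markers went from 0.366 to -0.092 (adjusted p = 0.708). Pdgfrb, a receptor of stellate cells, stood at 18.1 ± 5.07 against 8 ± 3.34 CPM (adjusted p = 0.154). Stab1, Lyve1, Oit3 and Eng among endothelial markers and Pdgfrb and Lox among stellate markers passed when adjusted over the list alone. Mitochondrially encoded genes (3.31e-06), interferon response (0.000951), NRF2 targets (0.00788), p53 response (0.0106), cell cycle (0.0192) and fatty acid synthesis genes (0.0229) were higher as well.

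Lower as groups at 22 °C in ablated mice were nuclear-encoded oxidative phosphorylation (35 of 36 negative, adjusted p = 3.31e-06), cytosolic ribosomal proteins (30 of 30 negative, 2.16e-05), drug-metabolising enzymes (20 of 25 negative, 0.000124) and pericentral genes (14 of 17 negative, 0.000707). Among drug-metabolising enzymes 7 were lower and 3 higher when adjusted over the list alone, with Cyp2c54 at 82.5 ± 55.5 against 395 ± 208 CPM (-2.29 ± 0.43, adjusted p = 0.0576). Male-biased genes (0.00117), heat shock proteins (0.00175), the acute phase (0.00228), the unfolded protein response (0.00238), gluconeogenesis (0.00399), erythroid genes (0.00756), bile acid genes (0.0319), neutrophil and platelet genes (0.0351) and glycolysis (0.0386) were lower too. Pck1 (-0.87 ± 0.23, adjusted p = 0.183) and Fgf21 (1.67 ± 0.67, adjusted p = 0.425) were not called, and Agtr1a (0.25 ± 0.11), Igf1 (-0.31 ± 0.14), Fasn (0.39 ± 0.23), Cirbp (-0.14 ± 0.16) and Rbm3 (-0.14 ± 0.16) had adjusted p of 0.471 or more. The count of 7 was 2 without 22 °C ablated male 2, 3 without 22 °C ablated female 2 and 25 without 22 °C ablated male 3. It was 11 without 22 °C ablated female 1, 12 without 30 °C ablated male 1 or female 1, and 35 without 30 °C ablated female 2, with 6 with sex additive, 1 with no sex term and 0 with Ai39 x BAC-AT1A-Cre mice alone and sex additive. Voom called 201 genes, and without the low-count filter DESeq2 called 159 and edgeR 493. Adamtsl2 stayed called without each library in turn.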

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

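The tests of sequencing depth and mouse line for the library with most genes at 0 reads, the tests that repeat the choice of a list in each split, and the look at clock genes in single libraries were chosen after the result was seen; the other tests were written before their results were seen.

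The search for a sample far from the others of its group needed at least 4 libraries, so it covered only the 4 control females at 30 °C. Libraries of the other groups, among them 30 °C control male 1, could not be flagged by it. Of 15 values tested, 1 was far: Agrp stood at 0.21 CPM in 30 °C control female 4 and at 0 in the other 3 control females, a gap of 1 times the range. With the others at 0 any single value above 0 gives this gap, so the nominal rate of chance flags does not apply. No explanation was tested, and such a count is close to the lower limit of detection.

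The other results listed here are differences between the effects of ablation in both temperatures or both sexes, by a test of the difference, among 111 such tests of lists; none passed with an estimated correlation (lowest adjusted p = 0.206). Between temperatures, the effect at 22 °C was the higher for fatty acid oxidation (adjusted p = 0.00942), stellate cells (3.37e-06), endothelium (0.00133), female-biased genes (0.0292) and NRF2 targets (0.00183), and the lower for the unfolded protein response (0.014), male-biased genes (0.0292), pericentral genes (0.00183) and erythroid genes (0.0236). Between sexes at 30 °C, the effect in females was the higher for heat shock proteins (0.0214), acute phase (0.000137), interferon response (0.0214), male-biased (0.00298) and ribosomal protein genes (0.0214). Between sexes at 22 °C, it was the higher for fatty acid synthesis (6.44e-10, and 0.000551 by fry for either direction), glycolysis (0.0465), the clock (0.000937), macrophages (0.006), drug-metabolising enzymes (0.0465), mitochondrially encoded genes (0.000487), pericentral genes (0.00359), erythroid genes (1.71e-06), neutrophil and platelet genes (0.0465) and adipocyte genes (0.0465). It was the lower for the acute phase (0.000177), female-biased genes (0.0079), the cell cycle (0.0079) and periportal genes (2.16e-07). As numbers of lists, chance could not be excluded for the difference between temperatures (9 lists, highest other split 22; 42 of 100 splits as many) or between sexes at 22 °C (14, highest other 22; 22 of 100) and 30 °C (5, highest other 19; 78 of 100).

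In the effect of ablation at 22 °C, 11 of 21 genes of fatty acid synthesis differed between the sexes when adjusted over the list alone. For this list 1 of 100 splits, the real one, reached 11 (highest other 10), but the list was chosen as the strongest, and with that choice repeated in each split chance could not be excluded: 21 of 100 splits had a list of as low an adjusted p (real 6.44e-10, lowest other 1.2e-21), and 7 of 100 a list with as many members (real 11, highest other 25). A difference in the time of day of tissue collection, tested through clock genes that peak early and late, could not be told apart from an effect of ablation. The early and late medians lay 0.29 apart on the log2 scale, but the 4 early genes ran from -0.54 to 0.80 with a median SE of 1.02, so a bound on that distance decides nothing. Single libraries moved with the pattern: of the 12 libraries at 22 °C, ablated males 1 and 2 had the lowest CPM of the late clock genes Ciart (12.8 and 6.36) and Per2 (60.9 and 32.7). They also had the lowest Fasn (330 and 396) and Acly (60.7 and 68.7), while ablated male 3 had 42, 92, 693 and 142 of these genes. The early gene Arntl was highest in ablated males 1 and 2 (3.02 and 2.74). The late gene Dbp was lowest in ablated male 2 (157), but ablated male 1 had 194, above control male 1 (172). A sex-dependent response to the ablation, for example through feeding, may be another explanation and remains a hypothesis that was not tested, with 3 mice per group. No control female at 22 °C carried Cre, so an effect of Cre in females was not separated from ablation either.

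The 19 genes called for ablation at 22 °C exceeded every other split of the 100 made (highest other 10, 1 of 100 as many). This argues against chance for the number of called genes only. At an unadjusted p under 0.05 the real split held 1685 genes and other splits up to 2205, so that number does not exclude chance. The Cre-positive and Cre-negative controls were compared over both temperatures, and the only Cre-positive control at 22 °C was a male. A Cre effect limited to 22 °C, or to females there, could therefore not be judged. A Cre effect common to both temperatures and sexes, as the whole cause, is argued against by these controls. Signed by the ablation effect, their median log2 difference in the 19 genes was 0.01 (-0.13 to 0.11 without each Cre-positive control). For ablation it was 1.36. Yet a term for Cre ended all 19 calls: the median log2 fold change, signed by the direction without it, was 1.37 with it and 1.36 without, but the median SE rose from 0.22 to 0.34 (lowest adjusted p = 0.111), as only 1 of 6 controls at 22 °C carried Cre. RNA quality, read as the share of mitochondrially encoded reads, is argued against. With the share as a covariate the median log2 fold change was 1 times that without it, and 18 of the 19 stayed called. That fit called 51 genes in all, so the share did bear on how many genes were called. Ablation itself may be the source of these 19 differences, and the virus was not tested apart from it. Nor was the time of day of tissue collection tested for these 19 genes.

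The library of 30 °C control male 1 had 0 reads in 6372 tested genes. Lower sequencing depth is argued against, as 0 reads were found in at most 2677 tested genes in the 4 libraries of no more reads. The mouse line (BAC-AT1A-Cre) is argued against, as its 2 other libraries had 0 reads in at most 2729. Fewer distinct molecules entering the library is a candidate explanation. In it, 3125 genes at a low level elsewhere summed to 0.9 times the CPM of the median library. Yet 50.7% of them had 0 reads (17.8% or less in the other libraries). Their ratio of variance to mean was the highest at 46.4 (next 36.4, in 30 °C ablated female 3, with 7.2% at 0 reads). The genes were chosen by their mean in the other libraries, which limits high values there but not here. The ratio alone therefore decides little. No biological explanation was tested, and as there was 1 other control male at 30 °C, results on that group rest on both.

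For the other comparisons, few splits matched the 568 genes that differed by sex (2 of 100 splits as many, highest other 973). The same held for the 24 lists of temperature in ablated mice (1 of 100, highest other 22). This argues against chance for both, with no allowance for the number of counts compared. For the 7 genes of temperature in ablated mice, 3 of 100 splits called as many, which is also few. At an unadjusted p under 0.05 the real split held the most genes (1977, highest other 1898). Other splits called up to 22 genes, however, so chance was not excluded for the 7 called genes. Their count was 0 with Ai39 x BAC-AT1A-Cre mice alone and sex additive. That fit kept only 3 of 6 ablated mice at 30 °C and was filtered anew, so it does not bear on chance alone. Chance could not be excluded for temperature in controls either, with 7 genes (10 of 100, highest other 294) and 6 lists (57 of 100, highest other 13). Nor could it be for the 17 lists of ablation at 22 °C (highest other 22; 10 of 100), the 5 lists of ablation at 30 °C (highest other 17; 79 of 100) or the 10 lists by sex (highest other 15; 23 of 100). Where edgeR called 0 genes, numbers at an unadjusted p under 0.05 were compared, and chance could not be excluded for ablation at 30 °C (1407, highest other 2850; 36 of 100). The same held for its difference from 22 °C (1414, highest other 2180; 12 of 100) and for the difference between sexes at 22 °C (1265, highest other 2205; 20 of 100) and 30 °C (1343, highest other 3283; 45 of 100).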

How the results depend on the processing

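All alternatives were planned before the data were examined, except limma voom with quality weights and the fit without the 3 libraries with most genes at 0 reads, which were chosen after the result was seen. Of 2187 recomputations of the 90 called lists, 1706 kept direction and call, 473 kept direction alone and 8 reversed. For the 70 called values of named genes, 1133 of 1472 kept the call and 339 kept direction alone, and for 427 values not called, 9716 of 10091 stayed so, 374 became called and 1 reversed. The cause was not tested unless given. DESeq2 ran without the low-count filter, and fits with Cre-negative controls, with Ai39 x BAC-AT1A-Cre mice or with only the groups compared were filtered anew. The fits with Cre-negative controls and with Ai39 x BAC-AT1A-Cre mice also took sex as additive, so none of these moves is credited to 1 choice.

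For ablation at 22 °C (19 genes), the number was 400 with no filter, 136 with DESeq2, 185 with voom, 49 with only the groups compared, 34 without the 3 libraries, 10 with Cre-negative controls and sex additive (15 with sex additive alone), 2 with no sex term, 0 with a Cre term, and 12 to 49 without each library in turn. For ablation at 30 °C (0 genes), it was 74 with no filter, 47 with DESeq2, and 0 to 817 without each library. For temperature in controls (7 genes), it was 273 with no filter, 268 with DESeq2, 1 with sex additive alone, with Ai39 x BAC-AT1A-Cre mice and sex additive, with a Cre term or without the 3 libraries, 0 with no sex term, Cre-negative controls and sex additive, only the groups compared or voom, and 0 to 1687 without each library. For temperature in ablated mice (7 genes), it was 493 with no filter, 159 with DESeq2, 201 with voom, 126 without the 3 libraries, 51 with only the groups compared, 12 with Cre-negative controls and sex additive, 6 with sex additive alone, 1 with no sex term, 0 with Ai39 x BAC-AT1A-Cre mice and sex additive, and 2 to 35 without each library. For the difference of the ablation effect between temperatures (0 genes), it was 191 with no filter, 14 with DESeq2, 2 without the 3 libraries, and 0 to 460 without each library; only the groups compared gave no separate value there, as all groups take part. For the difference between sexes at 22 °C (0 genes), it was 249 with no filter, 54 with DESeq2, 116 with voom, 42 with only the groups compared, 24 without the 3 libraries, and 0 to 5 without each library. At 30 °C (0 genes), it was 98 with no filter, 59 with DESeq2, and 0 to 813 without each library. For the sex difference (568 genes), it was 971 with no filter, 1119 with DESeq2, 367 with a log2 fold change of at least 1, 353 with only the groups compared, 312 with voom, and 319 to 1732 without each library. The genes shared by both ablation effects (0) were 18 with no filter, 9 at an unadjusted p under 0.01 and 1 with DESeq2. Across genes, r between both ablation effects was 0.033 to 0.365 over the alternatives run for it, the highest with a Cre term, which both effects then share. The called lists (90) were 2 with an estimated correlation and 4 with fry; their number was not counted with sex additive, a Cre term, Cre-negative controls, Ai39 x BAC-AT1A-Cre mice or without each library, where not all comparisons were fitted.

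With the replicate number as a block, which did not pair the libraries (median r between same numbers -0.007, best match of the same number in 6 of 24), the numbers were 17, 0, 7 for ablation at 22 °C, at 30 °C and temperature in ablated mice, 1 for temperature in controls, 2 for the difference between sexes at 22 °C and 435 for sex.

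The highest numbers without 1 library came from leaving out 30 °C control male 2, except for ablation at 22 °C (ablated male 3), temperature in ablated mice (30 °C ablated female 2) and the difference between sexes at 22 °C (control female 3). Male 1 then was the lone control male at 30 °C, assumed to vary like the other groups, and the median log2 fold change of all genes went from 0.053 to 0.164 for ablation at 30 °C, from 0.048 to 0.2 for temperature in controls and from 0.076 to 0.215 for sex. For the difference of the ablation effect it went from -0.053 to -0.186 between temperatures and from -0.094 to -0.338 between sexes at 30 °C. The lowest number for sex, 319, came without 30 °C control male 1. The reversed results all had an adjusted p of 0.448 or more except Fgf21, at 4.37 for temperature in controls without 30 °C control male 2 (adjusted p = 0.0176). Reversed lists, with directions relative to all genes by camera, are given as medians with the lowest and highest value without each library. Stellate cell markers (ablation at 30 °C) had 0.033 with Ai39 x BAC-AT1A-Cre mice and sex additive (-0.582 to -0.056), and macrophage markers (temperature in ablated mice) had -0.092 with the same (0.2 to 0.661). Ribosomal proteins (ablation at 30 °C) had 0.097 without 30 °C control male 2 (0.073 to 0.34), and male-biased genes (difference between temperatures) had -0.486 (-1.532 to -0.155). For the difference between sexes at 30 °C, male-biased genes had -0.311 without control male 1 and -0.505 without the 3 libraries (up to 1.416), and ribosomal proteins -0.053 and -0.134 (up to 0.434). Fgf21 had -0.637 to 4.366. In simulated libraries of this depth and size 54% of genes changed 2-fold were called for ablation at 22 °C. These genes averaged at least 1 CPM and varied independently of each other, so the share may not hold for the real libraries.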
